A study of Mus musculus with 18 samples.

How the data were processed

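Liver expression was measured in male mice fed a control diet or the same diet with 0.05% or 1% quercetin, a dietary flavonol, for 20 weeks. The labels give 12 mice per group housed 3 per cage, with arrays from 6 mice per group, each array holding the RNA of 1 mouse. The cage of each mouse was not in the labels, so cage was not a term in any model. The labels give the order of replicates no meaning. The 18 arrays were grouped by diet into control, 0.05% quercetin and 1% quercetin. The hybridised material was biotin-labelled amplified RNA from a 3-prime kit on an Affymetrix mouse array.

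The deposited values are linear intensity values, 1 probe set signal per array, from 0.0118 to 18108. The signal software and the scaling that the authors used are not given in the sources used here. The arrays were not on a common scale: the median over all probe sets lay between 14.2 and 22.0, and the trimmed mean between 99.5 and 152. The 45101 probe sets held 64 controls, 34945 with exactly 1 gene symbol, 932 with several and 9160 with none. Symbols were checked against a mouse annotation of assembly GRCm38.p6 by Entrez number, which matched 34741 probe sets and changed 0 symbols. Probe sets with several symbols or none were left out of the gene tests.

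Values were turned to log2 intensity after adding 16, and each gene was represented by its single-symbol probe set with the highest mean over the 18 arrays. Genes whose mean lay above the 40th percentile of all non-control probe sets, a log2 value of 4.69, entered the tests, which left 12885 genes. For a gene in a comparison where the naming rule below set it, the log2 change of its other probe sets above that value is given where 1 of them had the opposite sign or a size over 2 times larger or smaller. Other probe sets are not given for changes named after their values were seen. limma 3.58.1 under R 4.3.3 was fitted with lmFit and eBayes to 3 group means over all 18 arrays, with 15 residual degrees of freedom. The Benjamini-Hochberg adjusted p had to be under 0.05, two-sided, and fold changes are 1% against control, 0.05% against control and 1% against 0.05%. Tests were run on values as deposited, and the closing section gives the results after equalising the median of the tested genes and after quantile normalization. The prior degrees of freedom were 7.10, the median residual SD was 0.276 and the median standard error of a log2 fold change was 0.158. The number of arrays limits this precision. The pipeline was tested on simulated data with known changes added to these group sizes. Each simulation changed 50 genes at each log2 size of 0.5, 1, 1.5 and 2 at once. In the 3 comparisons, in that order, 80%, 92% and 96% of log2 changes of 1 were recovered, and 32%, 26% and 42% of changes of 0.5. The adjusted threshold is stricter where fewer genes change. These shares therefore do not give the chance of finding a single change of that size in the real data. Genes were simulated independently of each other, so the list test was not examined with correlated genes.

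Before the data were examined, 36 gene lists were fixed from textbook knowledge of liver, quercetin and the other cell types that a piece of liver could hold. Lists with 5 or more tested members, 35 of the 36, were tested with camera of limma at a preset correlation of 0.01 and adjusted over the lists. Camera with a correlation estimated per list and fry were run beside it. Each member was also tested with the p adjusted over the list alone. The list of mesothelium and capsule markers had too few tested members.

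The genes named in the text were set by a rule fixed before the data were examined. It took the 8 largest rises and 8 largest falls that passed, and the 10 genes with the smallest p where fewer than 5 passed, which held in all 3 comparisons. It added up to 4 members with the smallest p in each list that passed, and 20 preset genes in the comparison of 1% with control. Genes named outside that rule are marked as chosen after their values were seen. Counts of mice give those whose value lay beyond the mean of the other group in the direction of the change. The groups can overlap where all mice do so, and for genes picked by their p the count is not a further test.

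Alternatives chosen before the data were examined were quantile normalization, a median shift per array, no filter, a filter at the 60th percentile, a value of 1 in place of 16 added before the log2, eBayes with trend and robust, array weights, the mean of a gene's probe sets, only the 12 arrays compared, replicate number as a block, an adjusted p under 0.10, and leaving out each array in turn. Alternatives added after seeing the data were the mean of the acute phase list of each array as a covariate, and an exact permutation test of the list means per mouse. The list means used as the covariate and in the permutation test came from values after the median shift, as did the list means adjusted for it, while the gene values and lists tested with the covariate were those as deposited. Figures were drawn with matplotlib 3.10.9.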

Results

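Hepatic transcripts of 18 male mice were measured on Affymetrix arrays after 20 weeks of feeding, with 6 mice on the control diet, 6 on 0.05% quercetin and 6 on 1% quercetin. Expression is log2 of the deposited intensity plus 16, given as mean ± SD with n = 6 mice per group, and fold changes are log2 ± SE. The median of the 12885 tested genes differed between arrays by up to 0.53, with group means of 7.01 ± 0.13 in controls and 6.95 ± 0.17 at 1%. On values as deposited the median log2 change over all these genes was -0.06 for 1% against control, -0.01 for 0.05% against control and -0.05 for 1% against 0.05%. Counts of higher and lower list members below are taken against 0, not against these medians. Depth does not apply to arrays, and their number limits the precision. Xist lay between 4.69 and 5.51 and Eif2s3y between 8.76 and 9.97 on the 18 arrays.

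The comparison of 1% quercetin with the control diet asked how a high dietary intake of the flavonol altered liver transcription. As sets, genes of fatty acid oxidation and targets of PPARA, the nuclear receptor that induces them, rose, with 33 of 40 tested members higher and a median log2 change of 0.15 (adjusted p = 7.27e-11; adjusted p = 0.948 with an estimated correlation). Targets of NRF2, the transcription factor of the antioxidant response, rose as a set with 19 of 23 members higher and a median of 0.31 (adjusted p = 1.62e-09; adjusted p = 0.948 with an estimated correlation). Genes of fatty acid and triglyceride synthesis fell as a set with 24 of 31 members lower and a median of -0.37 (adjusted p = 0.000105; adjusted p = 0.948 with an estimated correlation). No single gene passed over all genes tested: limma called 0 of 12885, with 715 at an unadjusted p under 0.05 against 644 expected by chance.

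**Figure D1:**
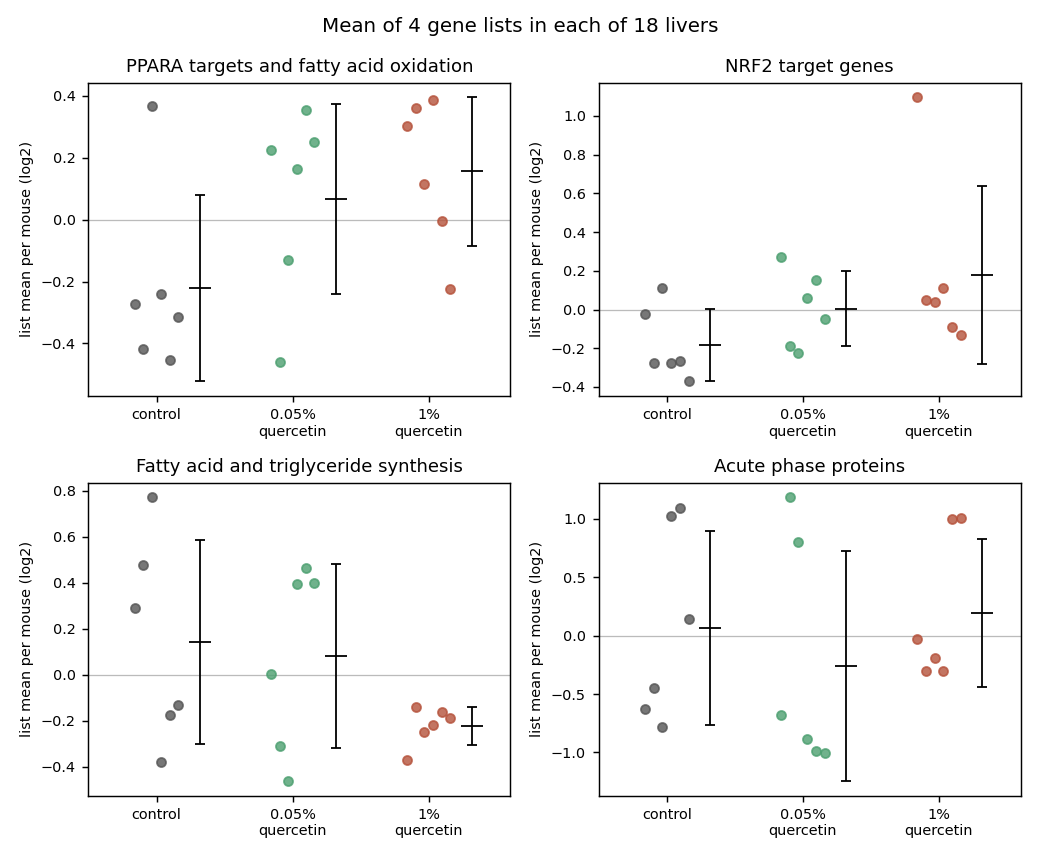
Mean of 4 gene lists in each mouse, in log2 units centred per gene after equalising array medians, by diet group, with points for mice and a black bar for the mean and SD beside them. The PPARA list averaged -0.22 ± 0.30 in controls and 0.16 ± 0.24 at 1%, the synthesis list 0.14 ± 0.44 and -0.22 ± 0.08, and a single mouse of the 1% group stands at 1.10 in the NRF2 panel.

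The gene nearest to the threshold was Gna14, which encodes a G protein alpha subunit, with 7.14 ± 0.59 in controls and 5.65 ± 0.49 at 1%, a log2 change of -1.49 ± 0.25 (adjusted p = 0.0781, lower in 6 of 6 mice). Gna14 passed without control replicate 3 (-1.67, adjusted p = 0.00916) or 1% replicate 6 (-1.66, adjusted p = 0.0137), and leaving out other arrays gave adjusted p-values up to 0.316. The next 9 genes by p each had an adjusted p of 0.337 and lay beyond the control mean in 6 of 6 mice. Osgin1, an oxidative stress-induced growth inhibitor and NRF2 target, measured 9.88 ± 0.32 in controls and 11.04 ± 0.62 at 1%, a change of 1.16 ± 0.26. Tead1, a transcription factor of the Hippo pathway, had a change of 0.56 ± 0.12 on its chosen probe set and -0.05 on its other one. After the median shift Tead1 passed at 0.61 (adjusted p = 0.0225), as it did after quantile normalization (adjusted p = 0.0118). Lower values, none of which passed, were found for Dio1, the deiodinase that activates thyroid hormone (-0.67 ± 0.15), Slc22a7, an organic anion transporter (-1.31 ± 0.30), and Ddit4, an inhibitor of mTORC1 (-0.997 ± 0.23). Dct, a melanin synthesis enzyme (-1.23 ± 0.25), Wfdc12 (-0.80 ± 0.18), Pls1, an actin-bundling protein (-0.84 ± 0.19), and Mras, a small GTPase (-0.92 ± 0.21, with -0.40 on another probe set), completed these genes.

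Among PPARA targets, 6 members were higher at an unadjusted p under 0.05, and 0 passed adjusted over the list alone or over all genes. Cyp4a14, a fatty acid omega-hydroxylase, measured 9.99 ± 1.37 in controls and 12.0 ± 0.59 at 1% (1.99 ± 0.68, higher in 6 of 6 mice). The acyl-CoA thioesterases Acot2 (1.04 ± 0.31, with -0.001 on another probe set) and Acot1 (1.10 ± 0.41), and Angptl4, an inhibitor of lipoprotein lipase (0.86 ± 0.35, with 0.09 on another probe set), were above the control mean in 6 of 6 mice. Among NRF2 targets, 1 of 23 passed adjusted over the list alone, Osgin1 (adjusted p = 0.00404), against 0 over all genes, and 2 were higher at an unadjusted p under 0.05. Gsta4, a glutathione transferase, had a change of 0.48 ± 0.23, Blvrb, a biliverdin reductase, 0.31 ± 0.15, and Cbr3, a carbonyl reductase, 0.63 ± 0.31, or 0.24 without 1% replicate 1. The median of the NRF2 list was 0.15 without 1% replicate 1 (adjusted p = 0.000852), and that of the PPARA list was 0.09 without 1% replicate 4.

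Of the synthesis genes, 4 of 31 passed adjusted over the list alone, against 0 over all genes, and 12 were lower at an unadjusted p under 0.05. They were Lpin1, a phosphatidate phosphatase (-1.42 ± 0.35), Thrsp, a lipogenic regulator (-1.74 ± 0.45), Dgat2, the acyltransferase that completes triglycerides (-0.49 ± 0.14), and Fasn, fatty acid synthase (-1.42 ± 0.46). Each lay below the control mean in 6 of 6 mice at 1%. Below all control mice lay 5 of 6 for Lpin1, 2 for Thrsp, 4 for Dgat2 and 2 for Fasn. Fasn measured 11.3 ± 1.16 in controls, 10.9 ± 1.11 at 0.05% and 9.89 ± 0.39 at 1%. The set's median was -0.24 without 1% replicate 1, and without control replicate 3 its call ended (adjusted p = 0.0858).

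For the other 4 sets that passed, the adjusted p was 0.948 with an estimated correlation. Their counts and medians stand beside a median change of -0.06 over all tested genes as deposited, which was -0.006 after the median shift. Genes of oxidative phosphorylation fell as a set, with 57 of 62 members lower and a median of -0.13 (adjusted p = 0.00379, 0 passing adjusted over the list alone). Ndufc2 (-0.25 ± 0.13, with 0.05 on another probe set), Atp5h (-0.21 ± 0.11, with -0.07 on another), Atp5g3 (-0.18 ± 0.10) and Sdhb (-0.28 ± 0.16) had the smallest p. Complement and coagulation genes were lower as a set, with 27 of 30 members lower and a median of -0.11 (adjusted p = 0.0192). In that list 1 member passed adjusted over the list alone, Masp1, a lectin-pathway protease (-0.53 ± 0.15, adjusted p = 0.0426, lower in 6 of 6 mice, with -0.32 to -0.14 on other probe sets), and F11 (-0.52 ± 0.21), Serpind1 (-0.24 ± 0.12) and C1s1 (-0.23 ± 0.12) followed. Genes of the unfolded protein response were lower as a set, with 20 of 25 members lower and a median of -0.21 (adjusted p = 0.0357, 0 adjusted over the list alone). Sel1l (-0.42 ± 0.16, with -0.38 to -0.12 on other probe sets), Edem1 (-0.39 ± 0.17), Atf4 (-0.32 ± 0.16) and Hsp90b1 (-0.27 ± 0.15) were among its members with the smallest p. Female-biased liver genes were higher as a set, with 8 of 12 members higher and a median of 0.07 (adjusted p = 0.0492, 0 adjusted over the list alone). Its leading members were Cyp4a14 and the thioesterase Acot3 (1.27 ± 0.69), which the PPARA list also holds, with Fmo2 (0.32 ± 0.17) and Cyp17a1 (-0.65 ± 0.38).

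After quantile normalization none of those 4 sets passed (median -0.04, adjusted p = 0.118 for oxidative phosphorylation, -0.03, 0.283 for complement, -0.13, 0.118 for the unfolded protein response and 0.11, 0.183 for female-biased genes). In the same order of median and adjusted p, the median shift ended the calls of the unfolded protein response (-0.16, 0.0640) and female-biased genes (0.12, 0.149). Array weights ended those of complement (-0.09, 0.172), the unfolded protein response (-0.15, 0.293) and female-biased genes (0.06, 0.0653). With 1 in place of 16 added the unfolded protein response call ended at an unchanged median (-0.21, 0.0710), and the female-biased call ended with no filter (0.05, 0.129) or, at an unchanged median, the replicate block (0.07, 0.0598). Without control replicate 1 or 3 the oxidative phosphorylation call ended (adjusted p from 0.0550 to 0.0866), and without control replicate 5 or 6 or 1% replicate 1 or 4 the complement call (0.0647 to 0.153). The oxidative phosphorylation median was -0.08 without 1% replicate 1, and that of complement was -0.17 without control replicate 3 and -0.07 without control replicate 5 or 1% replicate 1. The unfolded protein response call ended without control replicate 1, 4, 5 or 6 or 1% replicate 2 or 4 (0.0584 to 0.518), and its median was -0.07 without control replicate 6. The female-biased call ended without control replicate 1, 2, 5 or 6, 0.05% replicate 4 or 6, or 1% replicate 1, 2 or 5 (0.0521 to 0.229), and its median was -0.02 without control replicate 1, 0.02 without control replicate 2, 0.01 without control replicate 4 or 1% replicate 4 and 0.12 without control replicate 3 or 1% replicate 3.

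Of the unadjusted differences, 156 genes were higher and 559 lower, 21.8% higher. After the median shift there were 1099, with 499 higher and 600 lower, 45.4% higher, and after quantile normalization 1136, with 557 higher and 579 lower, 49.0% higher. The 28 sets that did not pass had adjusted p-values of 0.0602 or more, the smallest being those of male-biased genes and gluconeogenesis genes. None of the 10 tested lists of cell type markers was among those that passed (adjusted p of 0.223 or more).

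None of the 19 tested preset genes passed. Of NRF2 targets, Nqo1 had a log2 change of 0.03 ± 0.19, Gclc 0.36 ± 0.34, Gclm 0.22 ± 0.18 and Hmox1, heme oxygenase, 0.64 ± 0.39. Without 1% replicate 1, Gclc was at 0.05 and Hmox1 at 0.09. The antioxidant enzymes Cat (-0.17 ± 0.10), Sod1 (-0.09 ± 0.11) and Gpx1 (-0.14 ± 0.09) followed, and Sod1 was at 0.02 after quantile normalization and between -0.21 and 0.02 on other probe sets. Ppara itself was at -0.04 ± 0.19 (-0.24 and -0.07 on other probe sets) and Cpt1a, which admits fatty acids to mitochondria, at 0.09 ± 0.16. The drug-metabolising genes were at 0.02 ± 0.16 for Cyp1a1, -0.06 ± 0.15 for Cyp1a2, 0.00 ± 0.32 for Cyp2b10 and 0.02 ± 0.12 for Cyp3a11. Srebf1, the regulator of lipogenesis, was at -1.09 ± 0.49 and Scd1, a fatty acid desaturase, at -0.17 ± 0.09, with -0.87 on another probe set. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 0.21 ± 0.32 and Pck1, of gluconeogenesis, at -0.41 ± 0.34 (-0.41 and -0.05 on other probe sets), and without 1% replicate 1 they were at 0.04 and 0.03.

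**Figure D2:**
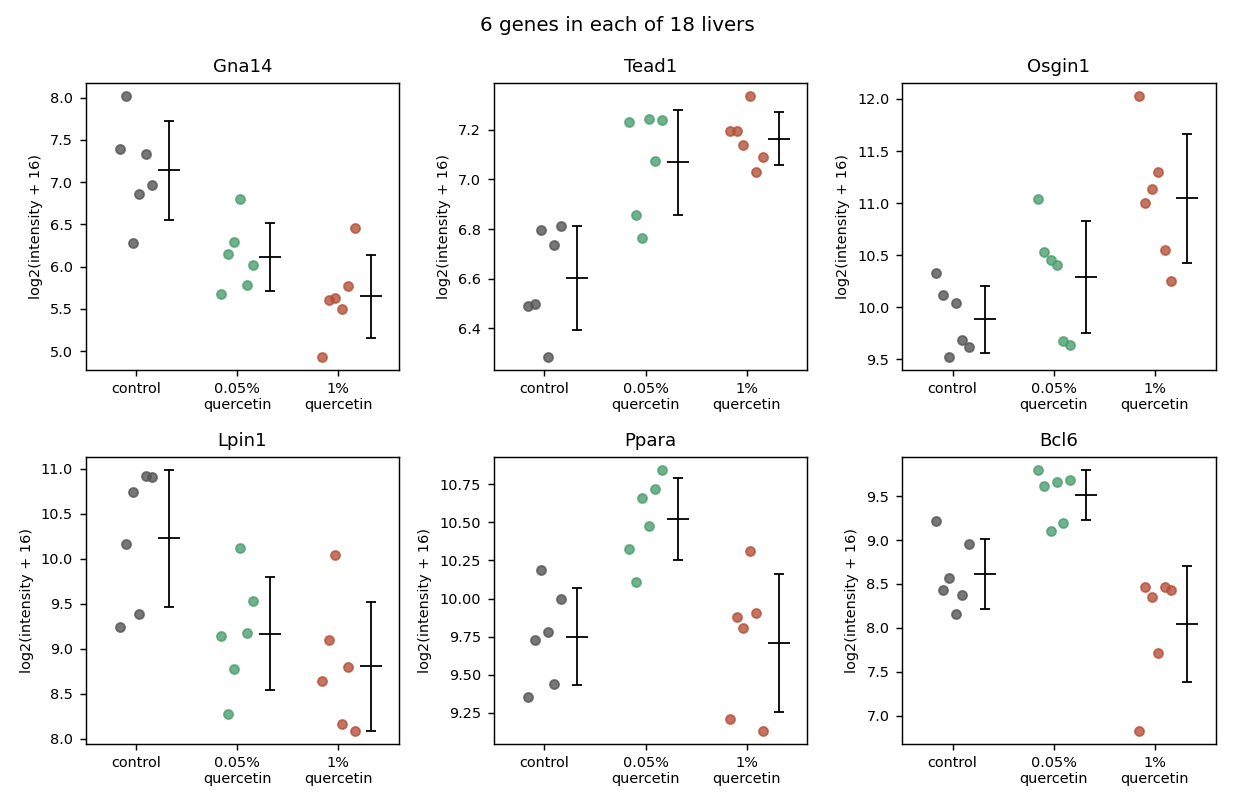
Log2 of intensity plus 16 of 6 genes in each mouse by diet group, with a black bar for the mean and SD beside the points. Gna14 averaged 7.14, 6.12 and 5.65 in the control, 0.05% and 1% groups, and Bcl6 8.62, 9.51 and 8.04; none of the 6 genes passed the adjusted test on values as deposited.

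The comparison of 0.05% quercetin with the control diet asked whether a low intake altered the same processes. PPARA targets rose as a set, with 34 of 40 members higher and a median of 0.12 (adjusted p = 3.45e-07; adjusted p = 0.904 with an estimated correlation). Ppara itself measured 9.75 ± 0.32 in controls and 10.5 ± 0.27 at 0.05% (0.77 ± 0.19, higher in 6 of 6 mice, with 0.29 and 0.37 on other probe sets) and was the 1 member that passed adjusted over the list alone (adjusted p = 0.0213), against 0 over all genes. Heat shock genes, the cytosolic chaperones, fell as a set, with 16 of 16 members lower and a median of -0.29 (adjusted p = 6.39e-06; adjusted p = 0.832 with an estimated correlation). After the median shift the mean of the heat shock list per mouse was -0.20 ± 0.56 at 0.05% and 0.14 ± 0.32 in controls (exact permutation p = 0.210). It ran from -0.78 to 0.51 at 0.05% and from -0.18 to 0.54 in controls, so the groups overlapped. NRF2 targets rose as a set, with 16 of 23 members higher and a median of 0.22 (adjusted p = 0.000367; adjusted p = 0.904 with an estimated correlation). No single gene passed over all genes: limma called 0 of 12885, with 394 at an unadjusted p under 0.05 against 644 expected by chance. Of these 184 were higher and 210 lower, and there were 656 after the median shift or 701 after quantile normalization.

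The genes with the smallest p were Rasl11b, a small GTPase (0.94 ± 0.19), and Resf1, a retroelement silencing factor (-1.03 ± 0.21, with -0.62 to -0.15 on other probe sets), both with an adjusted p of 0.392 and 6 of 6 mice beyond the control mean. Resf1 passed without 0.05% replicate 1 (-1.21, adjusted p = 0.0171). Plk3, a stress-response kinase, had a change of -1.29 ± 0.29, Errfi1, a feedback inhibitor of EGF receptor signalling, -0.55 ± 0.12, and the clock genes Per1 and Rorb -0.86 ± 0.21 and -0.60 ± 0.13. Gna14 measured 6.12 ± 0.40 (-1.02 ± 0.25), Ppp1r3c, a glycogen-targeting subunit of protein phosphatase, was at 1.52 ± 0.38, and Lonrf1 at -0.63 ± 0.17. In each of these genes 6 of 6 mice lay beyond the control mean, and none passed.

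The thioesterases Acot2 (0.85 ± 0.31, with 0.09 on another probe set), Acot1 (1.04 ± 0.41) and Acot3 (1.51 ± 0.69) led the PPARA list after Ppara, higher in 5, 5 and 4 of 6 mice. Among heat shock genes, with 0 passing adjusted over the list alone, Stip1 (-0.34 ± 0.13, lower in 6 of 6 mice), Chordc1 (-0.38 ± 0.16, 5 of 6), Hsph1 (-0.61 ± 0.28, 4 of 6) and Hspa8 (-0.40 ± 0.19, 4 of 6) led, and another Hspa8 probe set was at 0.15. In the NRF2 list 0 passed adjusted over the list alone, and Gsta2 (0.77 ± 0.33), Gsta4 (0.39 ± 0.23), Aox1 (0.39 ± 0.24) and Osgin1 (0.41 ± 0.26) led, each higher in 4 of 6 mice. Glutathione S-transferases rose as a set, with 12 of 19 members higher and a median of 0.15 (adjusted p = 0.0146; adjusted p = 0.929 with an estimated correlation; 0 adjusted over the list alone). Gstt2 (0.65 ± 0.29) and Mgst3 (0.39 ± 0.29) were among its members with the smallest p. Female-biased genes rose as a set, with 9 of 12 members higher and a median of 0.27 (adjusted p = 0.00338; adjusted p = 0.904 with an estimated correlation; 0 adjusted over the list alone). Fmo2 (0.36 ± 0.17), Cyp4a14 (1.29 ± 0.68) and Abcd2 (0.74 ± 0.56) were among its members with the smallest p.

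Of the 10 tested lists of markers of other cell types, 2 passed at this diet, and the other 8 had adjusted p-values of 0.234 or more. Neutrophil markers fell as a set, with 9 of 9 members lower and a median of -0.32 (adjusted p = 1.19e-05; adjusted p = 0.652 with an estimated correlation), with 1 passing adjusted over the list alone, Il1b, the inflammatory cytokine (-0.57 ± 0.18, adjusted p = 0.0448, lower in 6 of 6 mice). The calprotectin genes S100a8 (-1.34 ± 0.55) and S100a9 (-1.09 ± 0.51) and the granule gene Ngp (-0.36 ± 0.15) followed. Below all control mice lay 0 of 6 for Il1b, 1 for S100a8, 0 for S100a9 and 3 for Ngp. After the median shift the mean of the neutrophil list per mouse was -0.31 ± 0.21 at 0.05% and 0.18 ± 0.60 in controls (exact permutation p = 0.0952). Control replicates 4 and 5 stood at 0.99 and 0.83, and the other controls ran from -0.40 to 0.12, beside -0.69 to -0.11 at 0.05%. Endothelial markers were higher as a set, with 17 of 19 members higher and a median of 0.18 (adjusted p = 2.85e-05; adjusted p = 0.904 with an estimated correlation; 0 adjusted over the list alone). Vwf (0.31 ± 0.12), Cdh5 (0.26 ± 0.16), Clec4g (0.24 ± 0.15) and Flt1 (0.23 ± 0.15, with -0.01 on another probe set) had the smallest p. Cell cycle genes were higher as a set, with 17 of 26 members higher and a median of 0.13 (adjusted p = 0.00338; adjusted p = 0.929 with an estimated correlation; 0 adjusted over the list alone). Kif20a (0.62 ± 0.22), Ccna2 (0.48 ± 0.23), Cdc20 (0.79 ± 0.45, with -0.03 on another probe set) and Birc5 (0.43 ± 0.27) had the smallest p.

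A further 5 sets were lower, with 0 members passing adjusted over the list alone in each. Complement and coagulation genes were lower as a set, with 28 of 30 members lower and a median of -0.11 (adjusted p = 0.000108; adjusted p = 0.904 with an estimated correlation). Hc (-0.30 ± 0.14), C9 (-0.32 ± 0.17), Masp1 (-0.25 ± 0.15) and C2 (-0.35 ± 0.21) had the smallest p. The 4 other Masp1 probe sets lay from -0.19 to 0.18, and 3 of them had the opposite sign. Acute phase genes were lower as a set, with 22 of 24 members lower and a median of -0.18 (adjusted p = 0.000742; adjusted p = 0.929 with an estimated correlation). After the median shift the mean of that list per mouse was -0.26 ± 0.99 at 0.05% and 0.07 ± 0.83 in controls (exact permutation p = 0.530). Orm1 (-0.32 ± 0.17), Itih3 (-0.30 ± 0.17), Saa1 (-0.92 ± 0.67) and Itih4 (-0.16 ± 0.12) had the smallest p. Genes of the unfolded protein response were lower as a set, with 22 of 25 members lower and a median of -0.17 (adjusted p = 0.000742; adjusted p = 0.904 with an estimated correlation). Its leading members were Sel1l (-0.35 ± 0.16, with -0.35 to -0.005 on other probe sets), Hspa5 (-0.27 ± 0.15, with 0.05 on another probe set), Trib3 (0.54 ± 0.30) and Xbp1 (-0.23 ± 0.15, with -0.27 to -0.03 on others). Ribosomal protein genes were lower as a set, with 36 of 39 members lower and a median of -0.08 (adjusted p = 0.00352; adjusted p = 0.929 with an estimated correlation). Rpl27a (-0.18 ± 0.12), Rpl12 (-0.28 ± 0.22), Rpsa (-0.14 ± 0.12) and Rps6 (-0.16 ± 0.14) had the smallest p. Cholesterol synthesis genes were lower as a set, with 18 of 21 members lower and a median of -0.17 (adjusted p = 0.0191; adjusted p = 0.929 with an estimated correlation). Sqle (-0.81 ± 0.34), Mvd (-0.40 ± 0.30, with -0.09 on another probe set), Fdps (-0.32 ± 0.30) and Msmo1 (-0.35 ± 0.32) had the smallest p.

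After quantile normalization the calls of complement (median -0.07, adjusted p = 0.0599), acute phase (-0.18, 0.0831), ribosomal (-0.02, 0.603) and cholesterol synthesis genes (-0.15, 0.0816) ended. The cell cycle call ended with the filter at the 60th percentile (median 0.05, adjusted p = 0.105) or 1 in place of 16 added (median 0.09, adjusted p = 0.0512). The cholesterol synthesis call ended with 1 in place of 16 added (median -0.17, adjusted p = 0.0507) or the mean of a gene's probe sets (median -0.12, adjusted p = 0.0538). With the acute phase covariate, added after seeing the data, the call of glutathione transferases ended (median -0.01, adjusted p = 0.200). Leaving out 1 array ended the call of the unfolded protein response (0.05% replicate 5 or 6, adjusted p 0.0617 to 0.155) and of acute phase genes (control replicate 4 or 5 or 0.05% replicate 4, 5 or 6, 0.0838 to 0.200). It ended the call of cell cycle genes (control replicate 6 or 0.05% replicate 4, 0.0738 to 0.112), of female-biased genes (0.05% replicate 5, 0.0541) and of ribosomal genes (control replicate 5 or 6 or 0.05% replicate 5, 0.0617 to 0.0898). It also ended those of glutathione transferases (control replicate 4, 5 or 6 or 0.05% replicate 1, 4 or 5, 0.0771 to 0.229) and cholesterol synthesis genes (control replicate 1, 2 or 3 or 0.05% replicate 2 or 3, 0.0569 to 0.685). Without 0.05% replicate 4 the medians were 0.06 for PPARA targets, 0.12 for NRF2 targets, 0.10 for endothelial markers, 0.03 for cell cycle genes, 0.11 for female-biased genes, -0.30 for cholesterol synthesis genes and -0.02 for glutathione transferases. Without 0.05% replicate 2 they were 0.24 for PPARA targets, -0.33 for acute phase genes, 0.24 for cell cycle genes, 0.41 for female-biased genes, -0.04 for ribosomal genes, 0.26 for glutathione transferases and -0.03 for cholesterol synthesis genes. Without 0.05% replicate 5 they were -0.18 for heat shock genes, 0.08 for PPARA targets, 0.13 for NRF2 targets, 0.07 for cell cycle genes, 0.11 for female-biased genes and 0.07 for glutathione transferases. Leaving out 0.05% replicate 3 gave 0.19 for PPARA targets, 0.20 for cell cycle genes, 0.29 for glutathione transferases and -0.03 for cholesterol synthesis genes, and leaving out 0.05% replicate 6 gave 0.06, 0.06, 0.04 and -0.30 in that order. NRF2 targets were at 0.13 without 0.05% replicate 1. Of the controls, leaving out replicate 5 gave -0.19 for neutrophil markers, -0.09 for acute phase genes, -0.07 for complement genes, -0.04 for ribosomal genes and 0.09 for glutathione transferases. Leaving out control replicate 3 gave 0.18 for PPARA targets, -0.31 for acute phase genes, 0.43 for female-biased genes and 0.25 for glutathione transferases. Acute phase genes were at -0.28 without control replicate 1, cholesterol synthesis genes at -0.10 without control replicate 2, and cell cycle genes at 0.07 and glutathione transferases at 0.01 without control replicate 4. Without control replicate 6 the medians were -0.07 for the unfolded protein response and -0.03 for ribosomal genes. The 22 sets that did not pass had adjusted p-values of 0.0700 or more, the smallest being that of interferon-induced genes.

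**Figure D3:**
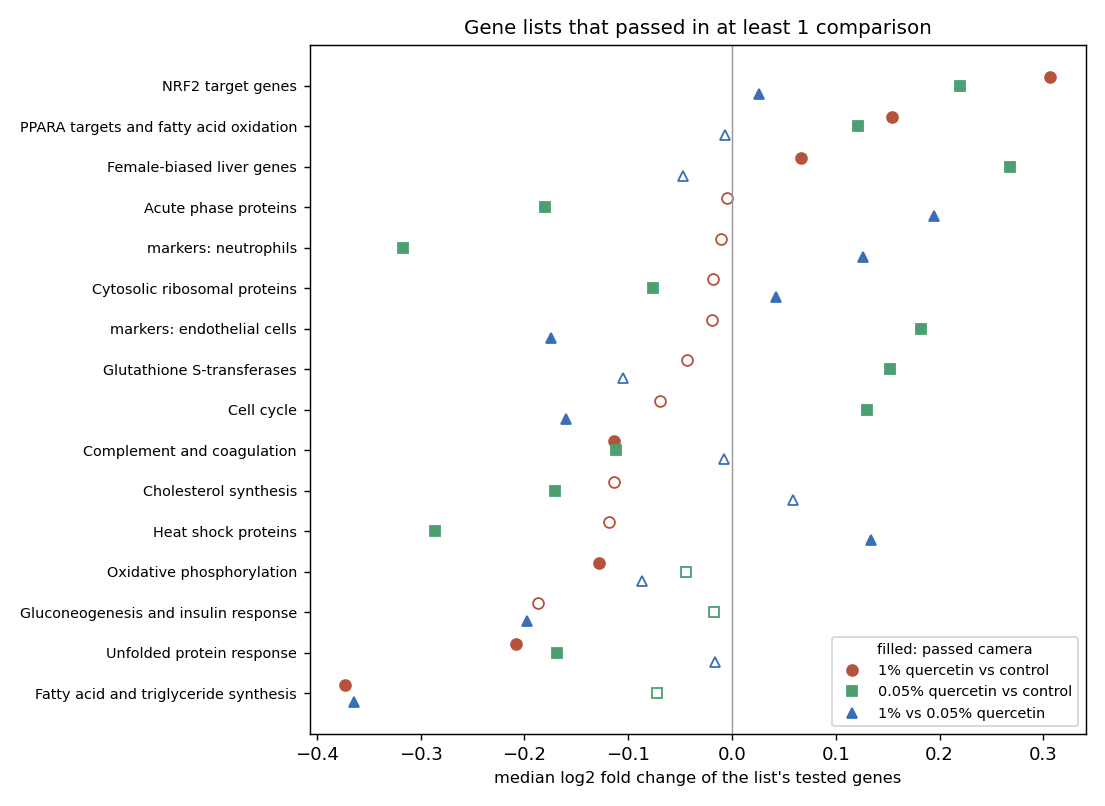
Median log2 fold change over the tested members of each of the 16 gene lists that passed camera in at least 1 comparison, with 1 marker per comparison, filled where the list passed. PPARA targets were at 0.15 for 1% against control and 0.12 for 0.05% against control, and synthesis genes at -0.37 for 1% against control and -0.36 for 1% against 0.05%; with an estimated correlation no list passed.

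The comparison of the 2 doses asked where the high intake differed from the low one. Genes of fatty acid and triglyceride synthesis fell as a set at 1% relative to 0.05%, with 27 of 31 members lower and a median of -0.36 (adjusted p = 0.00127; adjusted p = 0.925 with an estimated correlation). Acute phase genes, the liver's secreted response to inflammation, rose as a set, with 20 of 24 members higher and a median of 0.19 (adjusted p = 1.75e-05; adjusted p = 0.925 with an estimated correlation). After the median shift the mean of that list per mouse was 0.20 ± 0.63 at 1% and -0.26 ± 0.99 at 0.05%, so the groups overlapped. Bcl6, a transcriptional repressor that opposes PPARA at fatty acid oxidation genes, measured 9.51 ± 0.28 at 0.05% and 8.04 ± 0.66 at 1% and missed the threshold (-1.47 ± 0.24, adjusted p = 0.0552, lower in 6 of 6 mice). No gene passed: limma called 0 of 12885, with 708 at an unadjusted p under 0.05 against 644 expected by chance. The log2 ratio of 3-prime to 5-prime actin signal, a sign of RNA quality, was 1.24 ± 0.11 at 1%, 1.09 ± 0.08 at 0.05% and 1.18 ± 0.04 in controls, and that of Gapdh was -0.15 ± 0.08, -0.19 ± 0.12 and -0.09 ± 0.12. The 3 highest actin ratios of all arrays were those of 1% replicates 3, 4 and 1 (1.35, 1.34 and 1.32).

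Resf1 measured 6.99 ± 0.49 at 0.05% and 8.15 ± 0.44 at 1% (1.17 ± 0.21, adjusted p = 0.0764, higher in 6 of 6 mice, with 0.32 to 0.52 on other probe sets). It passed without 0.05% replicate 1 (1.35, adjusted p = 0.00322) or 1% replicate 5 (1.33, adjusted p = 0.00882). Bcl6 passed without control replicate 1 (-1.47, adjusted p = 0.0378), 1% replicate 1 (-1.22, adjusted p = 0.0307) or 1% replicate 5 (-1.55, adjusted p = 0.0265). Ass1, of the urea cycle, was at -1.22 ± 0.25 (adjusted p = 0.249). The other 7 of the 10 genes with the smallest p had an adjusted p of 0.364 and 6 of 6 mice beyond the other group's mean. Onecut1, a hepatocyte transcription factor, was at 2.13 ± 0.46 and Arid5b at 1.39 ± 0.31 (0.08 to 1.30 on other probe sets). Fbp2, a fructose bisphosphatase (-0.70 ± 0.15), the nuclear receptor Nr2f2 (-0.90 ± 0.21, with -0.68 to -0.13 on other probe sets), the growth arrest gene Gas1 (-1.64 ± 0.38), the transcription factor Snai2 (-1.44 ± 0.33, with -0.56 on another probe set) and the transcriptional coregulator Cited2 (-0.80 ± 0.19, with -0.34 on another) had lower values.

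Among synthesis genes 0 passed adjusted over the list alone, and Dgat2 (-0.38 ± 0.14), Thrsp (-1.16 ± 0.45), Fasn (-1.04 ± 0.46) and Gpam, which starts triglyceride synthesis (-0.77 ± 0.34), led. Genes of gluconeogenesis and the insulin response fell as a set, with 20 of 24 members lower and a median of -0.20 (adjusted p = 0.0297; adjusted p = 0.925 with an estimated correlation; 0 adjusted over the list alone). Tat (-0.89 ± 0.29), Ppp1r3c (-0.93 ± 0.38), Khk (-0.36 ± 0.19) and Igfbp1 (0.57 ± 0.34) were among its members with the smallest p. NRF2 targets passed as higher with 12 of 23 members higher and a median of 0.03 (adjusted p = 0.0171; adjusted p = 0.925 with an estimated correlation; 0 adjusted over the list alone). Osgin1 (0.76 ± 0.26), Txnrd1 (0.43 ± 0.21, with 0.09 and 0.22 on other probe sets), Cbr3 (0.54 ± 0.31) and Hmox1 (0.66 ± 0.39) had the smallest p. Without 1% replicate 1, Txnrd1 was at 0.22, Cbr3 at 0.15 and Hmox1 at 0.11. In the acute phase list, with 0 passing adjusted over the list alone, Cd14 (0.71 ± 0.31), Steap4 (1.23 ± 0.58), Itih3 (0.33 ± 0.17) and Saa1 (1.23 ± 0.67) were above the 0.05% mean in 6 of 6 mice.

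Heat shock genes rose as a set, with 13 of 16 members higher and a median of 0.13 (adjusted p = 0.000637; adjusted p = 0.925 with an estimated correlation). In that list 1 passed adjusted over the list alone, the small chaperone Hspb1 (1.10 ± 0.31, adjusted p = 0.0335, higher in 6 of 6 mice), followed by Hsph1 (0.52 ± 0.28), Stip1 (0.23 ± 0.13) and Hspa4l (0.30 ± 0.17, with -0.12 on another probe set). Ribosomal protein genes were higher as a set, with 33 of 39 members higher and a median of 0.04 (adjusted p = 0.00127; adjusted p = 0.925 with an estimated correlation; 0 adjusted over the list alone). Rpl12 (0.47 ± 0.22), Rpl35 (0.22 ± 0.12, with -0.13 on another probe set), Rps25 (0.25 ± 0.14) and Rpsa (0.15 ± 0.12) had the smallest p. Neutrophil markers were higher as a set, with 8 of 9 members higher and a median of 0.13 (adjusted p = 0.00344; adjusted p = 0.925 with an estimated correlation; 0 adjusted over the list alone), with S100a8 at 1.59 ± 0.55, S100a9 at 1.22 ± 0.51, Csf3r at 0.51 ± 0.26 and Elane at -0.26 ± 0.17. Endothelial markers were lower as a set, with 18 of 19 members lower and a median of -0.17 (adjusted p = 0.0104; adjusted p = 0.925 with an estimated correlation; 0 adjusted over the list alone). Clec14a (-0.43 ± 0.20), Cdh5 (-0.31 ± 0.16), Vwf (-0.22 ± 0.12) and Stab2 (-0.23 ± 0.15) had the smallest p. Cell cycle genes were lower as a set, with 22 of 26 members lower and a median of -0.16 (adjusted p = 0.0328; adjusted p = 0.925 with an estimated correlation; 0 adjusted over the list alone). Aurka (-0.57 ± 0.19), Kif20a (-0.53 ± 0.22), Cdc20 (-0.92 ± 0.45, with -0.05 on another probe set) and Mcm3 (-0.32 ± 0.19, with -0.42 and -0.02 on other probe sets) had the smallest p.

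The NRF2 call ended after the median shift (median 0.07, adjusted p = 0.102), after quantile normalization (median 0.06, adjusted p = 0.169) and without 0.05% replicate 2 or 3 or 1% replicate 1 (0.116 to 0.862), and its median lay from -0.09 to 0.14 with 1 array left out. That median was below 0 without 0.05% replicate 2 or 3 (-0.09 and -0.07) or 1% replicate 2 or 4 (-0.01 and -0.05). It was 0.14, 0.10, 0.12 and 0.06 without 0.05% replicate 1, 4, 5 or 6, and 0.02, 0.11 and 0.12 without 1% replicate 3, 5 or 6. Array weights turned its median to -0.10 and ended the call (adjusted p = 0.908). The gluconeogenesis call ended with 1 in place of 16 added (median -0.20, adjusted p = 0.0522), array weights (-0.23, 0.0866) or the mean of a gene's probe sets (-0.17, 0.0709). The cell cycle call ended with the filter at the 60th percentile (median -0.14, adjusted p = 0.316), 1 in place of 16 added (-0.17, 0.118), the mean of a gene's probe sets (-0.16, 0.0868) or only the 12 arrays compared (-0.16, 0.0633). With the acute phase covariate, added after seeing the data, the calls of synthesis genes (median -0.18, adjusted p = 0.0578), neutrophil markers (0.12, 0.0510), gluconeogenesis genes (-0.14, 0.0873) and cell cycle genes (-0.10, 0.208) ended. Leaving out 1 array ended the calls of endothelial markers (1% replicate 1, 0.0745), gluconeogenesis genes (control replicate 6, 0.05% replicate 1 or 6 or 1% replicate 4 or 6, 0.0507 to 0.261) and cell cycle genes (0.05% replicate 4 or 1% replicate 2, 5 or 6, 0.0710 to 0.232). Without 0.05% replicate 2 the medians were 0.38 for acute phase genes, 0.00 for ribosomal genes, -0.31 for gluconeogenesis genes and -0.32 for cell cycle genes, and without 0.05% replicate 4 they were -0.20 for synthesis genes, -0.10 for endothelial markers, -0.06 for cell cycle genes, 0.25 for neutrophil markers and 0.07 for ribosomal genes. Acute phase genes were at 0.34 without 0.05% replicate 3, 0.33 without 1% replicate 1 and 0.09 without 1% replicate 6. The heat shock median was 0.27, 0.22 or 0.07 without 0.05% replicate 1, 3 or 5, and 0.21 without 1% replicate 6. Ribosomal genes were at 0.07 without 0.05% replicate 6 and at 0.02, 0.06 or 0.03 without 1% replicate 4, 5 or 6. Neutrophil markers were at 0.23 or 0.19 without 1% replicate 1 or 2, endothelial markers at -0.10 without 1% replicate 1, and cell cycle genes at -0.24 without 0.05% replicate 3 and -0.29 without 1% replicate 4.

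Of the unadjusted differences between the doses, 241 genes were higher at 1% and 467 lower, 34.0% higher. After the median shift there were 1098, with 600 higher and 498 lower, 54.6% higher, and after quantile normalization 1167, with 649 higher and 518 lower, 55.6% higher. The 26 sets that did not pass had adjusted p-values of 0.0843 or more, the smallest being that of stellate cell markers.

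Across the tested genes, the log2 changes of the 2 doses against control had a covariance of 0.0141. Simulated groups with no change, compared with the same controls, gave 0.0142 on average, and 38 of 100 draws gave as much or more. The correlation across genes was 0.392 against 0.480 simulated, and 64.7% of genes had the same sign against 67.7% simulated. Genes are not independent replicates, and both comparisons share their control mice. With the 6 controls split into groups of 3, a separate group for each dose, the correlation averaged 0.00992 over 20 splits, from -0.413 to 0.233. A response common to both doses was therefore not detectable beyond what the shared controls gave.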

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

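The tests chosen only after the result was seen were those of the counts of passing genes over other splits, of the list means by exact permutation, of the acute phase covariate, of the NRF2 difference without 1 array, of acute phase differences between splits, of array brightness and of RNA degradation, while those of the counts at an unadjusted p, of the passing lists, of the list shifts over other splits and of the time of day were chosen before. Of 441 groups of 6 values examined, 30 held an array whose gap to its nearest neighbour took more of the group's range than the 95% critical value of Dixon's test, against 22.05 expected by chance, since about 5% of groups do so. The share of the range is given for each.

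PPARA and NRF2 targets were higher at both doses and fatty acid synthesis genes lower at 1%, and the question is whether the diet, the grouping by chance or the acute phase state of single mice accounts for it. Of 100 splits of the 12 arrays, the real one included, 4 gave a mean shift of synthesis genes at 1% as large as the real size of 0.415 (highest other 0.561). The splits used values as deposited, while the exact permutation used list means per mouse after the median shift, where the difference was -0.36. Over all 924 arrangements that permutation gave p = 0.0952 (adjusted p = 0.793), two-sided, with 0.00216 the smallest possible, so chance stays open there. For PPARA targets 10 splits were as large at 1% (0.327, highest other 0.431) and 23 at 0.05% (0.286, highest other 0.571), and for NRF2 targets 11 (0.311, highest other 0.409) and 24 (0.185, highest other 0.371), and the exact permutation, two-sided, gave p = 0.0411 (adjusted p = 0.556) for each at 1% and 0.156 and 0.117 (adjusted p = 0.682) at 0.05%, so chance was not excluded. With the acute phase mean of each array as a covariate the 1% differences were 0.41 (95% interval 0.18 to 0.64) for PPARA targets, 0.38 (0.03 to 0.74) for NRF2 targets and -0.32 (-0.60 to -0.04) for synthesis genes, beside 0.38, 0.36 and -0.36 without it, and at 0.05% they were 0.20 (-0.03 to 0.43) and 0.13 (-0.22 to 0.49), beside 0.29 and 0.19, while without 1% replicate 1, left out after seeing the data, the NRF2 difference at 1% was 0.20 (0.05 to 0.36), beside 0.18 (-0.04 to 0.40) without the covariate. For PPARA and NRF2 targets at 1% the differences were no smaller with the covariate. The acute phase means of these groups, 0.20 ± 0.63 at 1% and 0.07 ± 0.83 in controls, lay close together beside their spread. The adjustment could therefore change these differences little, and no conclusion on their source is drawn from it. For synthesis genes at 1% and both lists at 0.05% they were smaller with it, and a share due to acute phase state stays open. The intervals are those of the diet differences, and the bounds set for this test left each of them undecided. An effect of the diet remains a hypothesis found on these data.

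The acute phase list varied between mice of the same diet, from -0.78 to 1.09 in controls, -1.01 to 1.18 at 0.05% and -0.31 to 1.01 at 1%, which is not a difference between diets. Unequal brightness of the arrays was excluded, since after quantile normalization the within-group SD of 0.763 stood above all 1000 random lists of the same size (percentile 100), the highest of which had 0.143. The time of day of sampling stayed open: the slope of a clock gene difference on the acute phase mean was -0.10 (95% interval -0.83 to 0.62), too wide to decide. Around its mean over all arrays, that clock gene difference itself ran from -1.30 to 2.52 on the log2 scale. Neither infection nor injury was tested, and the design gives no group for a biological explanation. With the covariate the number of passing genes at 1% rose from 0 to 6 against control and from 0 to 3 against 0.05%. It stayed at 0 for 0.05% against control. A covariate that takes up spread within groups can raise this count by itself. The count therefore does not show that acute phase differences between mice enter the diet comparisons, which stays open for single genes.

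The array of 1% replicate 1 stood apart, at 38.5 on a second principal component that held 12.8% of the variance, and its NRF2 list mean was 1.10 against 0.27 for the next highest of any array. Of 23 NRF2 targets, 13 were highest on it against 1.28 expected by chance, and Srxn1 (4.84), Hmox1 (3.62), Cbr3 (2.77), Osgin1 (1.997) and Gclc (1.98) stood that far above the mean of the other arrays on the log2 scale. That expectation holds for an array picked blind and for independent genes, so the count describes this array and is not a test. RNA degradation beyond that of the other arrays was excluded, since its log2 ratio of 3-prime to 5-prime signal lay within their range for actin (1.32, range 0.990 to 1.35) and Gapdh (-0.11, range -0.32 to 0.07), and 1% replicates 3 and 4, with higher actin ratios of 1.35 and 1.34, had NRF2 means of 0.04 and 0.11. Unequal brightness was excluded too, since after quantile normalization the gap took 0.747 of the group's range. A strong oxidative stress response in this mouse may be the reason, and no biological explanation was tested as the design holds 1 such mouse.

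Further arrays far from their group are given by gene, with the array's log2 value, that of its nearest neighbour and the share of the range. In 1% replicate 1, Hmox1 stood at 10.69 (nearest 7.56, share 0.886), Cbr3 at 8.04 (6.04, 0.710), Pck1 at 9.73 (12.25, 0.913), Sdhb at 11.15 (11.50, 0.750), Clec14a at 5.47 (6.62, 0.759) and Flt1 at 5.80 (6.35, 0.640). In the same array Khk stood at 11.20 (11.63, 0.697), C9 at 12.45 (12.82, 0.644), the NRF2 list mean at 1.10 (0.11, 0.801) and the endothelial list mean at -0.22 (-0.04, 0.628).

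In control replicate 3, Abcd2 stood at 7.72 (nearest 4.72, share 0.946), Cyp2b10 at 6.202 (4.78, 0.690), Il1b at 5.89 (6.80, 0.681), Hc at 11.99 (12.59, 0.633) and C9 at 12.26 (13.12, 0.734). Its list means stood at 0.37 for PPARA targets (-0.24, 0.741), 1.01 for female-biased genes (-0.33, 0.8004) and -0.18 for complement genes (0.09, 0.699).

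In other controls, Sdhb in replicate 4 stood at 11.20 (nearest 11.81, share 0.768), Khk in replicate 4 at 11.28 (12.16, 0.818), Gclm in replicate 2 at 10.92 (11.37, 0.726) and Igfbp1 in replicate 6 at 10.06 (12.06, 0.722). At 0.05%, Acot1 in replicate 2 stood at 7.11 (8.71, 0.635), Cbr3 in replicate 2 at 5.12 (5.56, 0.750), Gpx1 in replicate 1 at 13.14 (12.999, 0.723) and Errfi1 in replicate 4 at 12.04 (12.53, 0.653). At 1%, Acot2 in replicate 4 stood at 8.71 (7.93, 0.642), Nqo1 in replicate 4 at 6.49 (6.08, 0.677), Cdc20 in replicate 4 at 7.83 (5.70, 0.6998) and Xbp1 in replicate 2 at 12.40 (12.52, 0.728).

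Among probe sets without a single gene symbol, which no gene test used, 4 of 4134 passed in the comparison of 1% with 0.05%, all lower at 1% with log2 changes from -1.18 to -0.76, and 2 passed after quantile normalization.

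Other splits of the 12 arrays, 100 per comparison with the real one included, did not exclude chance for the counts of genes at an unadjusted p under 0.05 or of passing lists. The counts of passing genes cannot be tested this way, since all 100 splits must give at least the real 0, and the highest of the other splits gave 363 at 1% against control, 316 at 0.05% against control and 24 at 1% against 0.05%. For 1% against control 33 splits gave as many genes at an unadjusted p under 0.05 as the real 715 (highest other 2499), and 81 gave as many passing lists as the real 7 (highest other 18). For 0.05% against control these numbers were 47 (394, highest other 3946) and 32 (13, highest other 20). For 1% against 0.05% they were 23 (708, highest other 3762) and 48 (9, highest other 16). Some splits gave several times the real number of genes at an unadjusted p under 0.05, which points to a structure of the samples. The first principal component held 24.7% of the variance, and the arrays at its ends were control replicates 5 and 4 (23.1 and 21.2, acute phase means 1.09 and 1.02) and 0.05% replicates 4 and 5 (-25.6 and -25.2, acute phase means -0.88 and -0.98). In the 10 splits with the most such genes, a choice made after seeing the data, the acute phase lists differed by a median of 0.31, 0.50 and 0.45 in the 3 comparisons, against 0.29, 0.31 and 0.20 in the others, so whether acute phase state is the source of that structure stays open.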

How the results depend on the processing

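The acute phase covariate and the exact permutation of list means were chosen after seeing the data. Genes passing at 1% against control went from 0 to 1 after quantile normalization or the median shift (Tead1), to 1 with the replicate block (Osgin1) or an adjusted p under 0.10 (Gna14), and to 6 with the acute phase covariate (Dio1, Moxd1, Retsat, Capn8, Acot2 and Gna14). At 1% against 0.05% they went from 0 to 1 with the filter at the 60th percentile (Bcl6), 2 with trend and robust or with an adjusted p under 0.10 (Bcl6 and Resf1), 7 with only the 12 arrays compared (Cdc42ep5, Onecut1, Bcl6, Arid5b, Snai2, Cish and Arid5a) and 3 with the covariate (Bcl6, Resf1 and Ass1). Fewer genes entered the 60th percentile filter, and an adjusted p under 0.10 is a looser threshold. With only the 12 arrays compared, the spread of the control mice no longer entered the fit, and the log2 changes were unchanged. There the SE was smaller for each of the genes that passed, as for Onecut1 (0.30 against 0.46), except Bcl6 (0.25 against 0.24). For the other settings the cause was not tested. Of 18 pairs of arrays with the same replicate number in different groups, 4 were the best match of the first array.

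After quantile normalization 4 lists passed at 1% against control, 3 of the 7 and cytosolic ribosomal proteins, and camera with an estimated correlation, fry, fry in either direction and the exact permutation gave 0 in each of the 3 comparisons, where fry gave 0, 1 and 0 lists and the permutation 3, 1 and 3 at an unadjusted p under 0.05. The estimated correlation had a median of 0.346 against the preset 0.01. The smallest adjusted p was 0.948, 0.652 and 0.925 with an estimated correlation, and 0.556, 0.606 and 0.0758 by exact permutation, two-sided, with a smallest possible p of 0.00216. With 35 lists, a single list at that p has an adjusted p of 0.0758. Neutrophil markers at 1% against 0.05% reached it, so the 0 by permutation says little in that comparison. Against control the smallest permutation p was 0.0411 at 1% and 0.0173 at 0.05%. Both lay above the smallest possible p, so that limit did not set the 0 there. Lists passing in all 3 scalings were 3, 9 and 8. The covariance of the changes of the 2 doses was 0.0311 with 1 added in place of 16, against 0.0318 on average for simulated groups with no change at that setting, a simulation added after seeing the data in which 47 of 100 draws gave as much or more.

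With 1 array left out, passing genes ranged from 0 to 1, 0 to 1 and 0 to 2 in the 3 comparisons, passing lists from 4 to 9, 8 to 14 and 8 to 12, and that covariance, with 16 added, from 0.0112 to 0.0228. The 1% against control change took the opposite sign for Nqo1 with array weights (-0.011; -0.054 to 0.128 with 1 array left out), Sod1 after quantile normalization (0.018) and Ppara after quantile normalization (0.023), the median shift (0.0092) or array weights (0.026; -0.162 to 0.073). It did so for Cyp1a2 after quantile normalization (0.017; -0.140 to 0.028) and Cyp3a11 with array weights (-0.018; -0.028 to 0.049). With 1 array left out the ranges were -0.0070 to 0.145 for Cpt1a, -0.105 to 0.077 for Cyp1a1, -0.106 to 0.306 for Cyp2b10 and -0.538 to 0.028 for Pck1. The causes were not tested.

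Of the 1705 values of named genes under other settings, 1682 kept their direction and side of the threshold, 16 passed and 7 changed sign. Of 375 values of lists, 280 did and 95 no longer passed. Genes near the filter value of 4.69 are limited by signal over background.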

Other observations

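The genes in this part were named after their values were seen, the fit of Moxd1 with the acute phase covariate was chosen after seeing the data, and no explanation is offered. In lists that did not pass, 4 genes at 1% against control, 5 at 0.05% against control and 5 at 1% against 0.05% passed adjusted over the list alone, and none passed over all genes. All 6 mice lay beyond the other group's mean in each, except Mvd with 5 of 6. At 1% against control they were Cyp39a1, an oxysterol hydroxylase (0.80 ± 0.22, adjusted p = 0.0409), Tat, of tyrosine breakdown (-1.16 ± 0.29, 0.0145), Mvd, of cholesterol synthesis (-1.04 ± 0.30, 0.0438), and the clock gene Per1 (-0.73 ± 0.21, 0.0376).

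At 0.05% against control they were the clock genes Per1 (-0.86 ± 0.21, adjusted p = 0.00760) and Nr1d1 (1.08 ± 0.33, 0.0354), Bcl6 (0.89 ± 0.24, 0.0221), Onecut1 (-1.67 ± 0.46, 0.0163) and Ppp1r3c (1.52 ± 0.38, 0.0163). At 1% against 0.05% they were Alas1, the first enzyme of heme synthesis (1.42 ± 0.35, 0.00884), its red cell form Alas2 (-0.34 ± 0.12, 0.0483), Ppara (-0.82 ± 0.19, 0.0124), Bcl6 (-1.47 ± 0.24, 7.29e-05) and Onecut1 (2.13 ± 0.46, 0.00144).

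Moxd1, a monooxygenase homologue, varied widely between mice, at 9.05 ± 2.83 in controls, 6.16 ± 3.16 at 0.05% and 5.53 ± 2.21 at 1%. Its change at 1% was -3.53 ± 1.32 (adjusted p = 0.803) as deposited and -3.94 ± 0.47 (adjusted p = 0.000433) with the acute phase covariate.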
